A study of Mus musculus with 20 samples.

How the data were processed

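Small RNA libraries from 20 mouse hearts were analysed: sham (n = 5), myocardial infarction (MI, n = 4), CIH (n = 4) and MI+CIH (n = 7). The labels give CIH as letters only, and it is read here as chronic intermittent hypoxia. Per the labels' protocols, hearts were flash frozen, RNA was extracted with Trizol and libraries were made from 3 µg of total RNA with a NEBNext small RNA kit. Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie and DESeq 1.8.3, with no role given for each; the miRBase release and the counting rules are not stated.

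The deposited table labels its values TPM, and by the values they are RPM, reads of a miRNA per 1000000 miRNA-assigned reads of the same library, as computed by the authors. No length enters them, each column sums to 1000000, and 100% of the values in each library were whole multiples of 1 read (tolerance 0.05 reads), so reads were recovered from them. The analysis plan, written before the data were examined, called the unit TPM. The table lists 1545 entries, of which 1427 carry miRBase names and 118 are predicted rows; 2 of the predicted rows were tested. Recovered reads summed to 1991323 to 18138415 per library, with 7.79% to 31.6% of them in second copies of other entries. A single-library value carries the counting error of its reads: among the values of single hearts picked out as far from their group the 95% interval was narrowest for miR-1a-3p in sham 1 (± 0.123%) and widest for miR-34c-3p in CIH 3 (2.32 RPM, 1.56 to 3.45). The lowest values they are compared with rest on 0 or 1 read and are less precise still.

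miRNAs with at least 5 RPM in at least 4 libraries were tested (360, holding at least 99.9% of reads). limma 3.58.1 in R 4.3.3 was fitted to log2(RPM + 1) with a mean per group over all 20 libraries (16 residual degrees of freedom, prior 5.90) and moderated with a trend, two-sided. p was adjusted by Benjamini-Hochberg over the miRNAs tested in each of 6 contrasts, with a threshold of 0.05: MI, CIH and MI+CIH each against sham, MI+CIH against MI and against CIH, and the interaction. Adjusted p without another tool named are from limma. In a sentence, "rose" and "fell" are used of miRNAs past the threshold. Because the main values are shares of a library, changes are also given relative to the median of the 360.

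Lists of miRNAs fixed in the plan (16: muscle-enriched, miR-199a/miR-214, raised in injured hearts, miR-29, miR-30, leukocyte, erythrocyte, endothelial, smooth muscle and mural, hypoxia, miR-17/92, let-7, miR-15/16, miR-23/27/24, Dlk1-Dio3, other tissues) were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, adjusted over all lists and contrasts, and also with the correlation estimated from the data.

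The miRNAs named in the text follow a rule of the plan: of those past the threshold with a mean of at least 50 RPM, the 10 with the largest change up and the 10 down; the 3 with the smallest p; 2 to 4 examples per list and members past the threshold; the 10 most abundant; and miR-214-3p, miR-21a-5p, miR-208b-3p, miR-210-3p and miR-223-3p in every comparison. Names outside it for a comparison, such as miR-208a-3p and miR-375-3p in MI+CIH against MI, were chosen after their values were seen, and not all are marked.

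Alternatives of the plan were pseudocounts of 0.5 and 5 RPM, no filter, a filter of a mean of at least 50 RPM, median-of-ratios and TMM scaling, sample quality weights, a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. limma stayed the main test because the table holds RPM and not counts. Chosen after seeing the data were a term for the library set (14 residual degrees of freedom, prior 5.34), set A alone, set B alone, removal of entries counted a second time, and leaving out sham 1 and MI 2 together. Library sets were found by clustering the libraries on log2(RPM + 1) and checked on the ratios of the 2 arms of 86 hairpins. Entries within 5% of each other in every library were checked against the GENCODE M21 annotation of GRCm38. Of 12 pairs, 7 overlap on opposite strands, 2 lie at separate places on the same strand without overlap, and 3 were not looked up.

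The pipeline was tested on simulated data with 360 miRNAs, 60 of them changed, in 10 runs. With the real set differences and 0 changed miRNAs, the fit without a set term called 167.1 on average in MI+CIH against sham, 139.9 against CIH, 17.3 in MI against sham and 0 in MI+CIH against MI; with the set term it called 0.1, 0.1, 0 and 0.1. The simulated set means contain infarction too, since sets B and C hold infarcted hearts only. With those set differences, the fit without a set term recovered 1.33% of 2-fold and 21.3% of 4-fold changes in MI+CIH against MI, and 0% and 0.333% in the interaction. With the set term, 36% of 2-fold and 91% of 4-fold changes were recovered in MI+CIH against MI, but 6.33% and 54.7% in MI+CIH against sham and 4% and 51.7% against CIH, so a count of 0 with the set term in those 2 leaves many changes of 2-fold undetected. camera was tested in 20 runs simulated without set differences, with each miRNA drawn independently and at an unadjusted p under 0.05. It called 20 of 20 lists of 9 members lowered 2-fold in MI+CIH and 1 of 20 unchanged lists. These runs say nothing about false list calls where members are correlated or sets differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. No library was left out of the main comparisons. The replicate numbers were not taken as pairs, since r between libraries of the same number ran from -0.711 to 0.867 over 25 pairs of groups and numbers.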

Results

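Small RNA from whole mouse hearts (strain C57BL/6J) was sequenced to measure microRNAs (miRNAs), short RNAs that repress messenger RNAs. The 20 libraries came from 5 sham hearts, 4 hearts after myocardial infarction (MI), 4 hearts after CIH and 7 hearts after both (MI+CIH). CIH is read here as chronic intermittent hypoxia, repeated short falls in inhaled oxygen that model the breathing pauses of sleep apnoea. The series title names the worsening of remodelling after MI by disordered breathing during sleep, so MI+CIH against MI is given first. The entries of each library summed to 1991323 to 18138415 reads, of which 7.79% to 31.6% were in entries that repeat the reads of another. 1 read was worth 0.0551 to 0.502 RPM, and 624 to 925 miRNAs had at least 1 read. A count of 0 reads allows up to 3 reads, or 0.165 to 1.51 RPM depending on the library, for counting error alone.

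The muscle miRNA miR-1a-3p had the highest mean over the 20 libraries, 21.96% of reads. The smooth muscle miRNA miR-143-3p followed at 17.6%, then miR-148a-3p at 4.02%, miR-378a-3p at 3.61% and miR-21a-5p, a miRNA of fibrosis, at 3.16%. This order is that of the pooled mean: miR-143-3p averaged more than miR-1a-3p in MI+CIH (159759 against 155624 RPM) and in set B (185856 against 120867 RPM), and miR-148a-3p more than miR-143-3p in set C (121710 against 31786 RPM). The others among the 10 with the highest mean were miR-30d-5p, miR-30a-5p, miR-26a-5p and miR-99a-5p, and miR-1b-5p at 21.9%. The miR-1b-5p values lay within 0.223% of those of miR-1a-3p in every library. Its hairpin Mir1b (GRCm38 chromosome 18, 10785446 to 10785567, plus strand) overlaps Mir1a-2 (10785481 to 10785552) on the minus strand, so both names count the same reads, and percentages here are of totals that hold both.

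The libraries fell into 3 sets that the labels do not name. Set A held all sham and CIH hearts with MI 2 and MI+CIH 1, set B held MI 1, MI 3 and MI+CIH 2 to 5, and set C held MI 4, MI+CIH 6 and MI+CIH 7. Pearson's r across miRNAs ran from 0.908 to 0.994 between libraries of the same set (73 pairs) and from 0.710 to 0.933 between sets (117 pairs). Clustering by the ratio of the 2 arms of 86 hairpins put 20 of 20 libraries in the same sets. Some abundant miRNAs differed between sets and others, such as miR-30a-5p (24000, 21789 and 23914 RPM in A, B and C), did not stand apart. miR-143-3p set only C apart, taking 13.4% to 26.1% of reads in set A, 12.8% to 26.9% in set B and 2.45% to 3.94% in set C. MI and MI+CIH hearts were in all 3 sets, whereas sham and CIH hearts were in set A alone, so each comparison is also given with the set as a term.

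**Figure D1:**
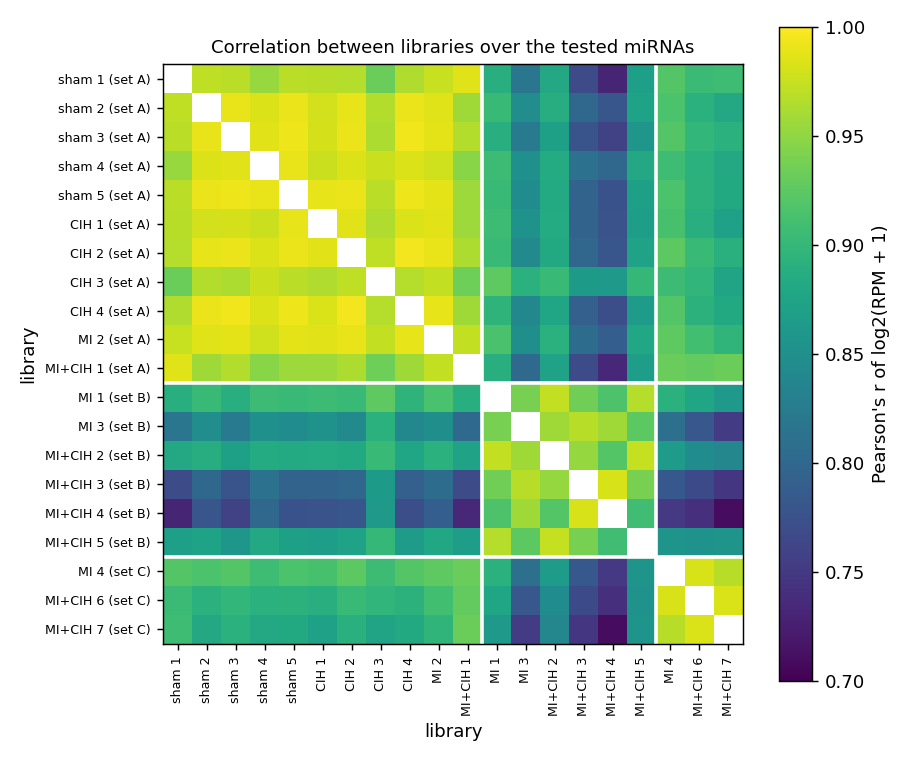
Pearson's r of log2(RPM + 1) over the 360 tested miRNAs for each pair of the 20 libraries, on both axes, ordered by set; colour gives r and the diagonal is left blank. The blocks on the diagonal are the 3 sets, with r of 0.908 to 0.994 within a set and 0.710 to 0.933 between sets.

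In hearts with MI+CIH, the muscle miRNAs as a group were lower relative to the other miRNAs than in hearts with MI alone. miR-1a-3p averaged 155624 ± 72780 RPM (SD, n = 7) in MI+CIH and 223269 ± 77947 RPM (n = 4) in MI, and lay below every MI heart of its own set in 7 of 7 MI+CIH hearts. Sets A and C hold 1 MI heart each, so MI+CIH 1, 6 and 7 are compared with 1 heart. In set A that heart is MI 2 (29.4% of reads), and an exchange of its label with sham 1 (18.9%) is left open below. MI+CIH 1 had 17.9%. miR-499-5p, encoded in the myosin gene Myh7b, averaged 908 ± 489 RPM against 1975 ± 1302 RPM, and was below every MI heart of its set in 6 of 7. miR-208a-3p, encoded in the alpha myosin gene Myh6 and named here after its values were seen, averaged 36.8 ± 37.996 RPM against 53.5 ± 34.5 RPM, also below in 6 of 7. miR-133a-3p averaged 11047 ± 7547 RPM against 10979 ± 8364 RPM, or 7266 RPM in MI without MI 1. It was below every MI heart of its set in 4 of 7 and above in 1, and miR-133a-5p was below in 5 of 7. Of the 9 tested members of the list 2 had a positive change, miR-208b-3p among them, and the remaining members were not counted within sets.

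None of the 9 tested members of the muscle-enriched list passed the threshold alone, over all miRNAs or adjusted over the list alone, while the list as a whole did. The list median was a log2 change of -0.59, which was -1.01 relative to the median of all miRNAs (0.41). The camera test gave an adjusted p of 1.96e-06, and 0.00812 with an estimated correlation. With the set as a term the adjusted p was 1.23e-06, or 0.0451 with an estimated correlation, and 3 members fell adjusted over the list alone. The list holds miR-1a-3p and its copy miR-1b-5p, so the same reads enter these tests under both names. Exchanging the MI and MI+CIH labels within sets, which has 90 arrangements, put the list median at -0.81 relative to all miRNAs in the real one, and 2 of 90 lay as far from 0 (exact permutation test, two-sided, p = 0.0222). In set A this test rests on MI 2, with the same doubt about its label.

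Some miRNAs outside the muscle list had higher means in MI+CIH than in MI, though 0 passed the test. miR-34b-3p and miR-34c-5p, of the p53-regulated miR-34 family (Mir34b, chromosome 9, 51103562 to 51103645, minus strand), averaged 33.7 ± 20.1 and 406 ± 361 RPM (n = 7) against 5.74 ± 4.78 and 60.7 ± 32.6 RPM (n = 4). miR-375-3p, known from endocrine and epithelial cells and named here after its values were seen, averaged 34.2 ± 32.4 against 6.77 ± 8.18 RPM. The erythroid miRNA miR-451a averaged 2876 ± 1729 against 611 ± 358 RPM and was above every MI heart of its set in 7 of 7 MI+CIH hearts. The erythrocyte list as a whole was not called (camera adjusted p 0.728) and lay -0.17 relative to all miRNAs. Of its members 6 of 6 had a positive change without the set term and 3 of 6 with it. miR-214-3p, from a fibroblast cluster, averaged 1059 ± 989 against 488 ± 532 RPM, and miR-21a-5p averaged 45542 ± 35334 against 15203 ± 5363 RPM. The ranges of mean ± SD overlapped for miR-34c-5p, miR-375-3p, miR-214-3p and miR-21a-5p, and not for miR-34b-3p and miR-451a. Of the MI means, that of miR-34b-3p was 3.47 and that of miR-375-3p 3.07 RPM without MI 1, and that of miR-214-3p 272 RPM without MI 3.

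limma called 0 miRNAs in MI+CIH against MI, with 17 at an unadjusted p under 0.05. edgeR and DESeq2 on the recovered reads also called 0. On simulated data with the real set differences this limma fit recovered 1.33% of 2-fold and 21.3% of 4-fold changes. The 3 smallest p were those of miR-451a (log2 change 2.43, SE 0.65, adjusted p 0.338), miR-34b-3p (2.24, SE 0.63, adjusted p 0.338) and miR-34c-3p (2.11, SE 0.63, adjusted p 0.371). With the set as a term limma called 2, both higher: miR-34b-3p (1.97, adjusted p 0.0284) and miR-375-3p (2.03, SE 0.42, adjusted p 0.0284), the latter named after its values were seen. They lay above every MI heart of their set in 6 and 7 of 7 MI+CIH hearts. Neither was called with the set term after median-of-ratios scaling, when 0 passed. For miR-214-3p and miR-21a-5p, named in the plan, the differences with the set term were 1.30 and 1.33, and exchanging labels within sets gave exact permutation p of 0.0778 and 0.133. miR-208b-3p, encoded in the beta myosin gene Myh7 (0.70, SE 0.72), and the hypoxia-inducible miR-210-3p (0.82, SE 0.59) had an adjusted p of 0.895 each.

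Among the other lists in MI+CIH against MI, 10 of 10 members of the list raised in injured hearts had a positive change, with 3 that rose adjusted over the list alone (camera adjusted p 0.00128; adjusted p = 0.404 with an estimated correlation). The leukocyte list had 8 of 9 members higher, among them the NF-kappaB target miR-146b-5p (log2 change 1.40, adjusted p 0.772) and the myeloid miR-223-3p (1.17, adjusted p 0.834), and 0 passed adjusted over the list alone. Its camera adjusted p was 0.0351, or adjusted p = 0.593 with an estimated correlation. The miR-30 family, abundant in heart muscle, lay -0.44 relative to all miRNAs with 0 of 11 members past either threshold (camera adjusted p 0.0121; adjusted p = 0.173 with an estimated correlation). In the imprinted Dlk1-Dio3 cluster, 36 of 36 members had a positive change and 0 passed either threshold (camera adjusted p 0.0358; adjusted p = 0.849 with an estimated correlation). Leaving out 1 heart ended 3 of these calls. The miR-30 call ended without MI 2 (0.0861) or MI 4 (0.0754). The leukocyte call ended without MI 1 (0.0971), MI 2 (0.0690), MI 3 (0.194), MI+CIH 1 (0.0558), MI+CIH 6 (0.0585) or MI+CIH 7 (0.198). The Dlk1-Dio3 call ended without MI 1 (0.0883), MI 2 (0.0861), MI 3 (0.114), MI 4 (0.0560), MI+CIH 1 (0.267), MI+CIH 2 (0.167), MI+CIH 6 (0.0632) or MI+CIH 7 (0.0549).

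**Figure D2:**
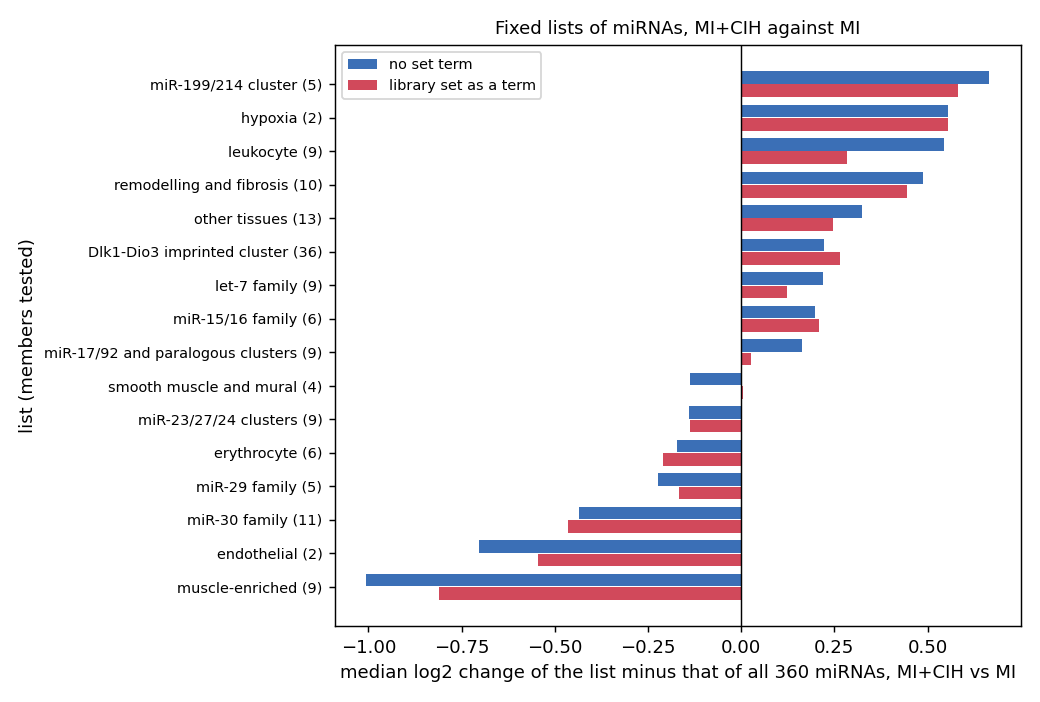
Median log2 change of each fixed list in MI+CIH against MI minus the median of all 360 miRNAs (horizontal axis), for the lists on the vertical axis with the number of members tested, without (blue) and with (red) the library set as a term. The muscle-enriched list lies lowest in both, at -1.01 and -0.81.

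**Figure D3:**
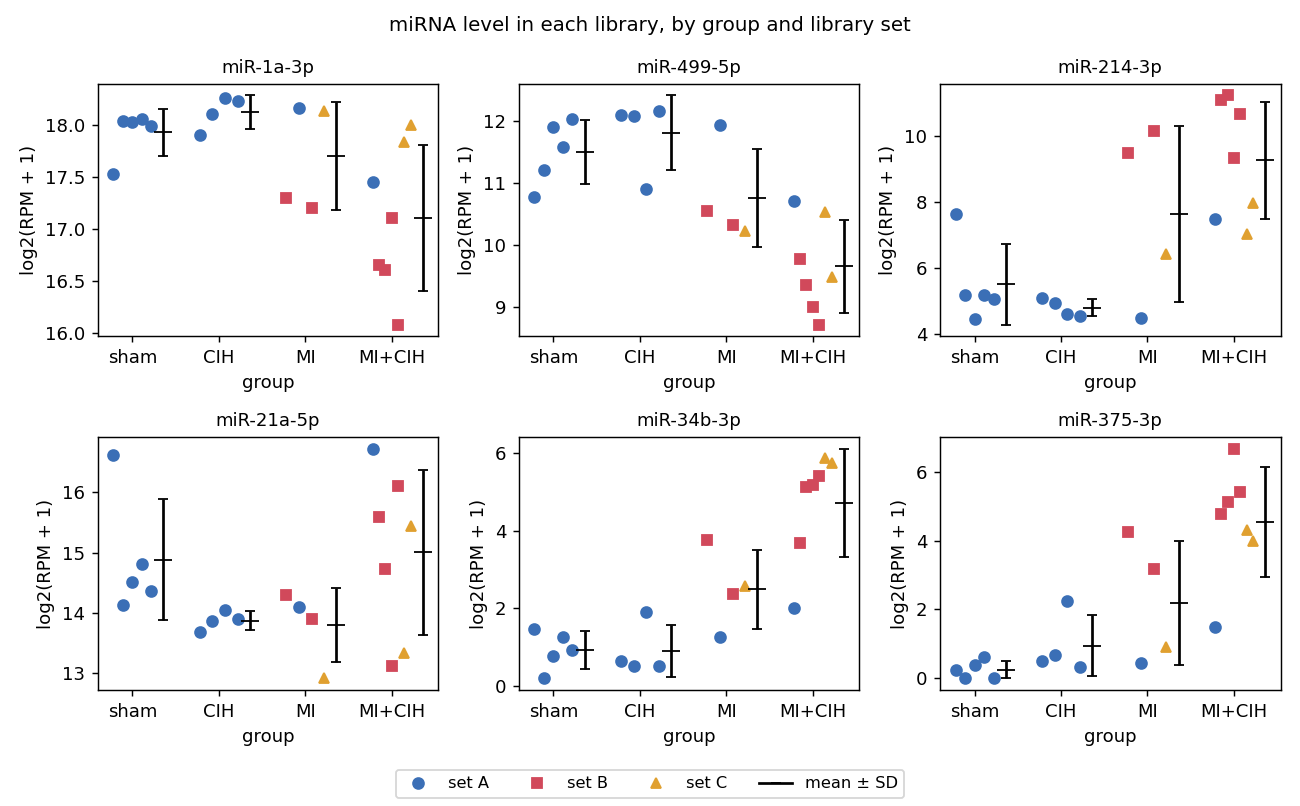
log2(RPM + 1) of 6 miRNAs (vertical axis) in each library by group (horizontal axis), with marker shape and colour giving the set and bars the mean ± SD of the group. miR-1a-3p in MI+CIH lies below the MI hearts of the same set in 7 of 7 hearts, where sets A and C hold 1 MI heart each. Sham 1 stands apart from the other sham hearts in miR-1a-3p, miR-214-3p and miR-21a-5p.

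In hearts with MI alone, the let-7 family, which restrains growth genes in differentiated tissue, lay above sham in 9 of 9 members without a set term; with it 6 of 9 did, and the list median went from 2.38 to 0.07. let-7i-5p averaged 6537 ± 3030 RPM (n = 4) against 1550 ± 778 RPM (n = 5), and let-7c-5p 8503 ± 5738 against 1062 ± 172 RPM. miR-351-5p averaged 41.4 ± 23.95 against 5.20 ± 1.24 RPM, and the inflammatory miR-146a-5p 730 ± 624.6 against 61.7 ± 29.7 RPM. miR-214-3p averaged 488 ± 532 against 64.5 ± 75.0 RPM, whereas miR-21a-5p averaged 15203 ± 5363 against 38326 ± 35015 RPM. Single hearts carried some of these means. Without sham 1 (198 and 100570 RPM) sham averaged 31.0 RPM of miR-214-3p and 22765 RPM of miR-21a-5p. Without MI 3, MI averaged 272 RPM of miR-214-3p, and without MI 4, 479 RPM of miR-146a-5p.

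limma called 0 miRNAs in MI against sham, with 101 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 39 (35 higher, 4 lower). The smallest adjusted p was 0.0701, shared by let-7i-5p (log2 change 1.996, SE 0.49), miR-351-5p (2.42, SE 0.61) and let-7g-5p (2.13, SE 0.54). These changes lay 1.06, 1.48 and 1.19 above the median of all miRNAs, which was 0.94 and fell to 0.17 under median-of-ratios scaling. miR-214-3p (2.13, adjusted p 0.175), miR-21a-5p (-1.08, adjusted p 0.222), miR-208b-3p (0.01, adjusted p 0.997), miR-210-3p (1.01, adjusted p 0.236) and miR-223-3p (0.78, adjusted p 0.268) did not pass. With MI 2 left out the count was 113, with MI+CIH 1 left out 31, and with sham 1 and MI 2 both left out, a choice made after the data were seen, 114 (108 higher, 6 lower). After adding the set as a term limma called 0, with 8 at an unadjusted p under 0.05, where set A, the only one with sham hearts, held MI 2 and MI+CIH 1 of the infarcted hearts.

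The let-7 list in MI against sham had 0 of 9 members past the threshold over all miRNAs, and 9 rose adjusted over the list alone (camera adjusted p 0.000253; adjusted p = 0.575 with an estimated correlation; 0.0659 with the set as a term). The miR-29 family, which represses collagen genes, lay -1.92 relative to all miRNAs with 0 of 5 members past either threshold (camera adjusted p 0.00701; adjusted p = 0.440 with an estimated correlation). Its members went both ways: miR-29a-3p had a log2 change of 0.29 and the list median was -0.98. The muscle-enriched list lay -1.17 relative to all miRNAs with 0 of 9 past either threshold (camera adjusted p 0.0482; adjusted p = 0.404 with an estimated correlation), its mean change of 0.17 had the opposite sign to its median of -0.23, and with the set as a term the direction was up (0.154). That call ended without sham 2 (0.0635), sham 3 (0.0665), sham 5 (0.0726), MI 1 (0.130), MI 3 (0.137), MI+CIH 1 (0.0637), MI+CIH 2 (0.0533) or MI+CIH 7 (0.0524). Of the erythrocyte list, 3 members rose and 2 fell adjusted over the list alone, with 0 of 6 past the threshold over all miRNAs (camera adjusted p 0.170). The 3 were miR-486a-5p, miR-486a-3p and miR-486b-3p, which are not independent (miR-486a-5p and miR-486b-3p lay within 4.26% of each other), the 2 were miR-144-3p and miR-144-5p, and miR-451a (-1.19) did not pass. After adding the set 0 of 6 members were higher, miR-486a-5p went from 2.27 to -0.34, and camera called the list lower (0.0158; adjusted p = 0.583 with an estimated correlation). That term also made the Dlk1-Dio3 cluster a call, higher (0.0454; 0.840 with an estimated correlation), and kept miR-29 lower (0.0158; 0.583).

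In hearts with CIH alone no single miRNA passed the threshold against sham. The largest separation by p was miR-363-3p, of the miR-106a-363 cluster (Mir363, chromosome X, 52741693 to 52741767), at 6.02 ± 4.67 RPM (n = 4) against 0.421 ± 0.288 RPM (n = 5). The erythroid miR-144-3p averaged 6.69 ± 4.63 against 18.5 ± 8.22 RPM. The hypoxia-inducible miR-210-3p averaged 4.15 ± 2.29 against 6.70 ± 3.12 RPM, and miR-210-5p was not past the threshold either, so 0 of the 2 hypoxia members passed over all miRNAs or adjusted over the list alone. miR-1a-3p averaged 287390 ± 31175 against 251938 ± 35396 RPM, and miR-214-3p 27.1 ± 5.16 against 64.5 ± 75.0 RPM, or 31.0 ± 6.83 RPM in sham without sham 1.

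limma called 0 miRNAs in CIH against sham, with 1 at an unadjusted p under 0.05, which was miR-363-3p (log2 change 1.86, SE 0.87, adjusted p 0.998). The other small p were those of miR-144-3p (-1.51, SE 0.78) and miR-214-5p (-1.17, SE 0.70), both at an adjusted p of 0.998. miR-214-3p (-0.71), miR-21a-5p (-1.01), miR-208b-3p (0.55), miR-210-3p (-0.65) and miR-223-3p (-0.43) had the same adjusted p. Without sham 1 the sham mean went from 38326 to 22765 RPM for miR-21a-5p and from 14.7 to 7.93 RPM for miR-208b-3p. edgeR called 0 (7 at an unadjusted p under 0.05), and DESeq2 called 1, miR-363-3p. All hearts of both groups were in set A, so the set term left each change as it was and altered the spread; limma then called 0, with 15 at an unadjusted p under 0.05. In simulated data with the real set differences and no changed miRNA, 0 were called on average.

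Across lists, all 5 members of the miR-199a/miR-214 list, among them miR-199b-5p, were lower in CIH than in sham, at -0.82 relative to all miRNAs, with 0 past either threshold (camera adjusted p 0.0121; adjusted p = 0.445 with an estimated correlation). The hairpins Mir199a-2 and Mir214 (chromosome 1, 162223368 to 162223477, plus strand) lie in Dnm3os, a transcript antisense to Dnm3. The miR-15/16 family, which restrains the cell cycle, lay -0.38 relative to all miRNAs with 0 of 6 past either threshold (camera adjusted p 0.0149; adjusted p = 0.593 with an estimated correlation). The Dlk1-Dio3 cluster was lower in 33 of 36 members with 0 past either threshold (camera adjusted p 0.00249; adjusted p = 0.607 with an estimated correlation). Without sham 1 the adjusted p was 0.213 for miR-199a/miR-214 and 0.935 for Dlk1-Dio3, and 0.0551 for Dlk1-Dio3 without CIH 4. Adding the set term, the adjusted p was 0.0203 for miR-199a/miR-214, 0.0206 for Dlk1-Dio3 and 0.0711 for miR-15/16, which was no longer called, and miR-29 became a call, lower (0.0266); with an estimated correlation these were 0.583, 0.811, 0.771 and 0.583. The miR-15/16 call was lost without sham 4 (0.0741), CIH 1 (0.0527) or CIH 3 (0.0579).

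In hearts with both MI and CIH, 9 of 9 let-7 members rose against sham, as did 4 of 5 of miR-199a/miR-214 and 6 of 9 of the leukocyte list, while 5 of 9 muscle-enriched entries fell and 1 rose; with the set as a term 0 of these passed. miR-206-3p, a skeletal muscle miRNA, averaged 141 ± 155 RPM (n = 7) against 0.118 ± 0.0743 RPM (n = 5), where sham 5 had 0 reads, which allows up to 0.439 RPM. miR-455-3p, from an intron of the collagen gene Col27a1, averaged 176 ± 131 against 8.29 ± 4.64 RPM. miR-146a-5p averaged 1132 ± 768 against 61.7 ± 29.7 RPM, miR-214-3p 1059 ± 989 against 64.5 ± 75.0 RPM and let-7b-5p 6912 ± 6635 against 295 ± 64.6 RPM. miR-101a-3p averaged 2795 ± 4628 against 10247 ± 3141 RPM, and miR-499-5p 908 ± 489 against 3048 ± 1013 RPM. The MI+CIH mean of miR-101a-3p was 1062 RPM without MI+CIH 1, and that of miR-206-3p 92.1 RPM without MI+CIH 5. miR-206-3p was uneven among infarcted hearts, at 2.44 RPM in MI+CIH 1 and 20.1 to 437 RPM in MI+CIH 2 to 7. Among MI hearts it was 370 RPM in MI 3 against 0.138 to 2.29 RPM in MI 1, 2 and 4. Its tissue source was not tested. The sham mean of miR-214-3p was 31.0 RPM without sham 1.

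limma called 204 miRNAs in MI+CIH against sham, of which 188 rose and 16 fell. The median change of all miRNAs was 1.39, and 0.17 under median-of-ratios scaling, which called 64 higher and 50 lower, 80 of them shared with the 204. Relative to the median, the largest rises among miRNAs with a mean of at least 50 RPM were miR-206-3p (log2 change 5.83, 4.44 above the median), miR-455-3p (3.91, 2.52 above), miR-146a-5p (3.83), let-7e-5p (3.80), miR-214-3p (3.75), let-7b-5p (3.73), miR-200c-3p (3.71), let-7c-5p (3.43), miR-34c-5p (3.36) and miR-125a-5p (3.28), with adjusted p from 0.000490 to 0.00299. The largest falls were miR-101a-3p (-2.97, -4.36 relative to the median), miR-101b-3p (-2.03), the heart-abundant miR-22-3p (-1.89), miR-499-5p (-1.84), miR-208a-3p (-1.82), miR-30e-5p (-1.71), miR-192-5p (-1.55), miR-126a-5p of endothelium (-1.53) with its copy miR-126b-3p, and miR-133a-5p (-1.21), with adjusted p from 0.00272 to 0.0323. Several of these falls turned with the set as a term (miR-101b-3p 0.0015, miR-30e-5p 0.57) or in set A alone (miR-101a-3p 0.42, miR-101b-3p 0.40, miR-208a-3p 0.17, miR-30e-5p 0.78). The smallest adjusted p, 0.000490, was shared by miR-34b-3p (3.81, SE 0.59), let-7i-5p (2.63, SE 0.43) and miR-375-3p (4.29, SE 0.72). miR-21a-5p (0.12, adjusted p 0.863) and miR-208b-3p (0.71, SE 0.67) did not pass. These 204 calls lie along the sets, since 6 of 7 MI+CIH hearts and no sham heart were outside set A. With the set as a term limma called 0, with 21 at an unadjusted p under 0.05, and in set A alone 2 were called lower (miR-690 and 1 predicted row). There the MI+CIH arm is 1 heart, assumed to vary like the other groups.

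By list in MI+CIH against sham, the let-7 family rose in 9 of 9 members, for example let-7f-5p (2.52), with 9 adjusted over the list alone (camera adjusted p 0.00188; adjusted p = 0.593 with an estimated correlation). The muscle-enriched list had 1 member that rose, miR-133a-3p (1.60, 0.21 relative to the median), and 5 that fell, among them miR-1a-3p (-0.82) and its second copy miR-1b-5p, with the same counts adjusted over the list alone (camera adjusted p 0.000223, 0.0290 with an estimated correlation; 0.385 with the set as a term and an estimated correlation). In the miR-29 family 1 of 5 fell, miR-29c-3p (-1.82), also adjusted over the list alone (camera adjusted p 0.0134; adjusted p = 0.516 with an estimated correlation). The list raised in injured hearts had 9 of 10 that rose, such as miR-224-5p (3.11), and 9 adjusted over the list alone, while miR-21a-5p did not pass (0.12; camera adjusted p 0.0681). The miR-199a/miR-214 list rose in 4 of 5 members and 4 adjusted over the list alone, yet did not stand out from all miRNAs (camera adjusted p 0.478). Of the leukocyte list 6 of 9 rose, and 7 adjusted over the list alone (camera adjusted p 0.426), among them miR-155-5p (2.72) and miR-223-3p (1.95). Of the Dlk1-Dio3 cluster 24 of 36 rose, and 24 adjusted over the list alone (camera adjusted p 0.138), for example miR-127-3p (2.69). Given the set term, camera also called Dlk1-Dio3 higher (0.00242, 36 of 36 members), the list raised in injured hearts higher (0.0203) and miR-30 lower (0.0158), none of them with an estimated correlation (0.771, 0.583 and 0.385).

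The remaining lists in MI+CIH against sham were not called by camera without the set term. Of the list of other tissues, 9 of 13 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p 0.541). Among them were the epithelial miR-200c-3p (3.71), the liver miRNA miR-122-5p (1.98) and miR-375-3p. The list did not stand out from all miRNAs, and with the set as a term 0 of 13 rose and 8 of 13 had a positive change. Of the erythrocyte list 3 rose, all entries of miR-486, such as miR-486a-5p (2.51, but -0.48 with the set as a term and in set A alone), and 1 fell, miR-144-3p (-1.67), with 3 and 2 adjusted over the list alone (camera adjusted p 0.509). Both hypoxia members rose, miR-210-3p (1.83, adjusted p 0.0114) and miR-210-5p (2.04), as they did adjusted over the list alone, and under median-of-ratios scaling miR-210-3p lay at 0.62 (adjusted p 0.341). Of the endothelial pair, miR-126a-5p fell and miR-126a-3p (0.11) did not pass, over all miRNAs or adjusted over the list alone. In the smooth muscle and mural list 1 of 4 rose, miR-145a-5p (1.65), also adjusted over the list alone (camera adjusted p 0.403), and miR-143-3p (-0.86) did not pass. The miR-17/92 clusters of proliferation had 3 of 9 that rose, among them miR-92a-3p (2.97), and 3 adjusted over the list alone (camera adjusted p 0.798). The miR-23/27/24 clusters had 5 of 9 that rose, and 5 adjusted over the list alone (camera adjusted p 0.851), the miR-15/16 family 2 of 6 and 1 (0.636), and the miR-30 family 1 that fell and 0 (0.0668).

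**Figure D4:**
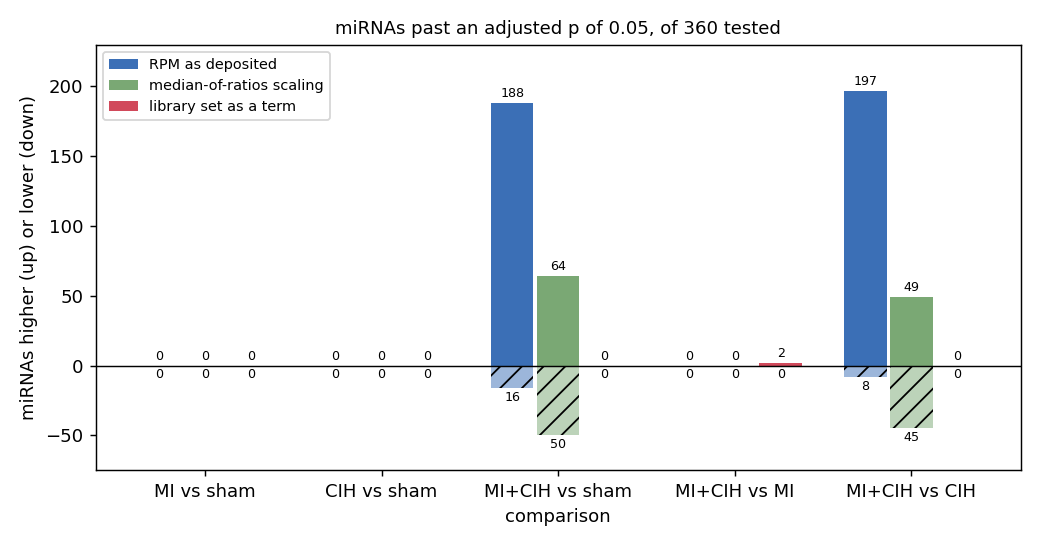
Number of the 360 tested miRNAs past an adjusted p of 0.05 in each comparison (horizontal axis), higher above 0 and lower below it (hatched), on RPM as deposited (blue), after median-of-ratios scaling (green) and with the library set as a term (red). MI+CIH against sham has 188 higher and 16 lower as deposited, 64 and 50 after scaling, and 0 with the set term.

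The comparison of MI+CIH with CIH alone uses the same 7 MI+CIH hearts, and CIH hearts lie in set A as sham hearts do, so it is no independent repeat of the one above. miR-214-3p averaged 1059 ± 989 RPM (n = 7) against 27.1 ± 5.16 RPM (n = 4), miR-206-3p 141 ± 155 against 1.22 ± 2.35 RPM, and miR-223-3p 42.5 ± 28.9 against 5.96 ± 0.614 RPM. miR-210-3p averaged 33.0 ± 24.9 against 4.15 ± 2.29 RPM. miR-1a-3p averaged 155624 ± 72780 against 287390 ± 31175 RPM and miR-499-5p 908 ± 489 against 3816 ± 1267 RPM. Without CIH 3 the CIH mean of miR-206-3p was 0.0466 RPM, and without MI+CIH 5 that of MI+CIH was 92.1 RPM.

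limma called 205 miRNAs in MI+CIH against CIH, of which 197 rose and 8 fell, with a median change of 1.51 over all miRNAs. Median-of-ratios scaling called 49 higher and 45 lower, 57 of them shared with the 205. The largest rises were miR-206-3p (log2 change 5.31, 3.80 above the median), miR-214-3p (4.46), let-7e-5p (4.27), miR-146a-5p (4.23), miR-574-5p (3.90), let-7b-5p (3.89), miR-34c-5p (3.82), miR-455-3p (3.77), let-7c-5p (3.58) and miR-200c-3p (3.55), with adjusted p from 0.00112 to 0.00351. The falls with a mean of at least 50 RPM were miR-101a-3p (-2.31), miR-499-5p (-2.16, -3.67 relative to the median), miR-192-5p (-1.38), miR-126b-3p (-1.18), miR-126a-5p (-1.17), miR-1b-5p and miR-1a-3p (both -1.02), with adjusted p from 0.00199 to 0.0280. miR-101a-3p turned with the set as a term (0.53) and in set A alone (1.08), as did miR-192-5p in set A alone (0.0102). The smallest adjusted p, 0.000712, was shared by miR-34b-3p (3.83), miR-146b-5p (3.10) and miR-541-5p (3.58). miR-210-3p (2.49, adjusted p 0.00272) and miR-223-3p (2.38, adjusted p 0.00199) rose, while miR-21a-5p (1.13, adjusted p 0.103) and miR-208b-3p (0.16) did not pass. After adding the set as a term limma called 0, with 62 at an unadjusted p under 0.05, and in set A alone it called 0.

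By list in MI+CIH against CIH, 1 muscle entry rose, miR-133a-3p, and 3 fell, miR-499-5p and the 2 copies miR-1a-3p and miR-1b-5p, with the same counts adjusted over the list alone (camera adjusted p 4.82e-06, and 0.00812 with an estimated correlation; 0.384 with the set as a term and an estimated correlation). The let-7 family rose in 9 of 9, and 9 adjusted over the list alone (camera adjusted p 0.00459; adjusted p = 0.593 with an estimated correlation; 0.162 with the set as a term). The list raised in injured hearts rose in 9 of 10, and 9 adjusted over the list alone (camera adjusted p 0.0298; adjusted p = 0.593 with an estimated correlation; 0.0873 after median-of-ratios scaling). Without MI+CIH 1 (0.0558) or MI+CIH 7 (0.0524) it was not called. The Dlk1-Dio3 cluster rose in 29 of 36, and 32 adjusted over the list alone (camera adjusted p 0.0121; adjusted p = 0.748 with an estimated correlation; 0.0803 without MI+CIH 1). The miR-30 family had 1 of 11 that rose and 0 adjusted over the list alone, and lay -1.09 relative to all miRNAs (camera adjusted p 0.0338; adjusted p = 0.283 with an estimated correlation). The miR-30 call was lost without CIH 4 (0.0659), MI+CIH 1 (0.0637) or MI+CIH 7 (0.0508). Lists of other cell types, not called by camera, also held members past the threshold. In them 6 of 9 leukocyte, 3 of 6 erythrocyte, 1 of 4 smooth muscle and mural and 8 of 13 other-tissue members rose (camera adjusted p 0.426, 0.541, 0.346 and 0.830). Of the other tissues 1 fell, as did 1 of the endothelial pair, and with the set as a term 0 of these passed. Fitted with the set, camera called Dlk1-Dio3 (6.34e-05), the list raised in injured hearts (0.0185) and miR-199a/miR-214 (0.0153; 0.138 without the term) higher and miR-30 lower (0.0128), none of them with an estimated correlation (0.611, 0.583, 0.583 and 0.385).

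Whether CIH went with different changes in infarcted and in sham hearts was tested as an interaction, the change from MI to MI+CIH minus the change from sham to CIH. miR-21a-5p differed by a log2 value of 2.21 (SE 0.87), miR-451a by 2.40 (SE 0.95) and miR-34c-5p by 2.72 (SE 1.09), the 3 smallest p, each with an adjusted p of 0.880. miR-214-3p (2.34, SE 1.41), miR-208b-3p (0.15), miR-210-3p (1.48) and miR-223-3p (1.60) did not pass either. limma, edgeR and DESeq2 each called 0, with 14 at an unadjusted p under 0.05 in limma and 13 in edgeR. With the set as a term limma called 0, with 66 at an unadjusted p under 0.05, and in set A alone it called 2, miR-142a-3p of leukocytes and its copy miR-142b, both higher and named after their values were seen. The MI and MI+CIH arms there are 1 heart each, assumed to vary like the other groups. The muscle-enriched list was lower in this difference, at -1.29 relative to all miRNAs, with 0 of 9 members past either threshold (camera adjusted p 4.82e-06, and 0.00812 with an estimated correlation; 0.0711 with the set as a term and an estimated correlation).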

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

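Apart from the camera tests of the fixed lists, which were in the plan, the tests in this part were chosen after the result was seen. A test of the highest and lowest heart of each group picked out single hearts below. Chance alone picks out about 1 in 20 groups, and 27 of 196 were picked out here. The 27 include second copies of the same reads and hearts outside the library set of the rest of their group, so they are not independent.

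Sham 1 stood apart from the other 4 sham hearts. It was the highest for let-7i-5p (2924 RPM, others 1072 to 1391), miR-214-3p (198, others 21.0 to 35.5), miR-21a-5p (100570, others 17878 to 28616), miR-208b-3p (41.7, others 6.49 to 10.1), miR-455-3p (16.5, others 5.398 to 7.03) and miR-146b-5p (194, others 76.7 to 96.0). It was the lowest for miR-1a-3p (189056, others 261221 to 272753) and for miR-1b-5p, which counts the same reads (188930).

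In MI 2, let-7i-5p (2114 RPM, others 7061 to 8712), miR-351-5p (6.28, others 47.7 to 60.1) and miR-541-5p (5.94, others 49.8 to 71.8) were far below the other MI hearts. In MI+CIH 1, let-7i-5p (3012, others 8175 to 12902), let-7g-5p (1332, others 6229 to 9385), miR-351-5p (7.77, others 25.6 to 59.3), miR-541-5p (14.2, others 54.2 to 105) and miR-99a-5p (6165, others 21333 to 39086) were far below the other MI+CIH hearts. MI 2 and MI+CIH 1 are the only hearts of their groups in set A, so these gaps lie along the sets. For example, miR-351-5p was 3.86 to 7.41 RPM in sham and CIH hearts, and the set A mean of miR-99a-5p was 6503 RPM. In MI 3, miR-451a was low (95.7 RPM, others 669 to 916) and the predicted rows took 1.52% of reads (others 0.00232% to 0.154%).

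In CIH 3, miR-101a-3p (2100.06 RPM, others 8474 to 9642), miR-101b-3p (410, others 1179 to 1333), miR-499-5p (1923, others 4348 to 4598), miR-126a-5p (488, others 1503 to 1764), its copy miR-126b-3p (488) and miR-133a-5p (143.2, others 333 to 385) were far below the other CIH hearts. miR-206-3p (4.74, others 0 to 0.140), miR-34b-3p (2.71, others 0.417 to 0.559) and miR-34c-3p (2.32, others 0.0844 to 0.167) were far above them.

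In the interaction, camera at the preset correlation called 5 lists, though without the set term 0 of their members passed either threshold. The camera adjusted p was 4.82e-06 for the muscle-enriched list (lower in the difference), 0.0111 for miR-199a/miR-214 (5 of 5 members higher; 0.0858 without MI 1), 0.00249 for the list raised in injured hearts (9 of 10 higher), 0.0300 for miR-30 (lower) and 0.00136 for Dlk1-Dio3 (36 of 36 higher; 0.0630 without sham 1). With an estimated correlation these were 0.00812, 0.440, 0.440, 0.283 and 0.593, so the muscle-enriched list alone stayed called. With the set as a term and an estimated correlation its camera adjusted p was 0.0711. The miR-30 call was lost without sham 1 (0.0788), MI 2 (0.126), MI 4 (0.0919), CIH 2 (0.0516), CIH 4 (0.113) or MI+CIH 3 (0.0730).

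The first pattern weighed is that of the 3 library sets. Depth is excluded as its source, since thinning every library to 1991323 reads moved 0 libraries to another set. Leaving out miR-1a-3p, miR-1b-5p and miR-143-3p also moved 0. That test cannot decide on a few abundant miRNAs, since correlations of log values hardly change with a few rows or with a shift common to all others. CIH alone does not account for the sets, since all 3 hold both MI and MI+CIH hearts. A difference in library preparation or processing is a candidate explanation, and the arm ratios of 86 hairpins put 20 of 20 libraries in the same sets. The ratios cannot decide on it, since they were taken from the same values that defined the sets. With 1 RPM added to each arm, the ratio of a hairpin with 1 arm near the floor also moves with its level. Sets B and C hold infarcted hearts only, so infarction is not told apart from preparation here. Whether the rises in MI+CIH against sham follow infarction or the set cannot be told apart, because 1 MI+CIH heart alone lies in the set of the sham hearts: there the called miRNAs had a median log2 difference of 0.55 from the sham mean, against 1.30 to 3.17 in the other 6.

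The second pattern is sham 1, which lay apart from the other sham hearts. For residual blood, its miR-451a was low, at 307 RPM against 914 to 3078 RPM in the other sham hearts. The erythroid miR-144-3p (14.8 RPM) lay within those hearts (7.42 to 26.9), and the myeloid miR-223-3p (12.9 RPM) above them (6.48 to 10.2). More red cells are thus not seen, but these few miRNAs cannot exclude blood. For exchanged labels of sham 1 and MI 2, on the mean log2 value of the remodelling and miR-199a/miR-214 lists, MI 2 had 4.55, within the 4.28 to 4.68 of sham 2 to 5, and sham 1 had 6.02, below the 6.15 to 6.51 of MI 1, 3 and 4. Sham 1 also lay outside those 3 hearts for miR-21a-5p (7732 to 20198 RPM), miR-208b-3p (4.90 to 22.1 RPM) and let-7i-5p, and the library closest to it was MI+CIH 1 (r = 0.986). An exchange of labels and an injured sham heart cannot be told apart, since no other MI heart is in set A, and the groups were kept as labelled.

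The third pattern is the higher miR-34b/c and miR-375-3p in MI+CIH than in MI within sets, noticed in the data. miR-34b/c are abundant in ciliated epithelium and miR-375-3p in endocrine and epithelial cells, so tissue carried over with the heart may be the source. The 6 epithelial members of the list of other tissues were higher by 1.0002 on the log2 scale with the set as a term (exact permutation p = 0.278). Epithelium and a change in the heart itself cannot be told apart, since the difference lies between 0 and that of miR-34b/c (2.03) and its spread is wide.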

How the results depend on the processing

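The library set as a term, set A alone, set B alone, removal of second copies, leaving out sham 1 and MI 2 together, and every alternative run with the set term were chosen after the data were seen; the others were in the plan. Unless a reason is given, the cause of a change was not tested.

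Counts of called miRNAs were within 1.5 times the reported ones, or 0 in both, in 49 of 66 planned cases. The reported count was 0 in MI against sham, CIH against sham, MI+CIH against MI and the interaction, where only another 0 matched. Where miRNAs were called, pseudocounts of 0.5 and 5 RPM (203 and 201 in MI+CIH against sham, 204 and 201 against CIH), only the groups compared (185, 181) and the replicate block (218, 211) left the counts within 1.5 times. Both scalings, edgeR and the filter of a mean of at least 50 RPM left both counts outside it. In the order MI+CIH against sham, then against CIH, scaling and tools gave 114 and 94 (median-of-ratios), 109 and 95 (TMM), 85 and 75 (edgeR) and 146 and 133 (DESeq2). Of the 204, 80, 75, 62 and 118 were kept. DESeq2 also called 39 in MI against sham and 1 in CIH against sham (miR-363-3p). With fewer miRNAs tested (mean of at least 50 RPM, 166) the counts were 14 in MI against sham, 92 and 94; with no filter (1416 tested) 135 and 166. Sample quality weights called 261 in MI against sham, 2 in CIH against sham (miR-208b-3p, miR-363-3p), 306 and 308, and 1 in MI+CIH against MI (miR-206-3p); the weights did not converge.

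With the set as a term, MI+CIH gave 0 against sham, 0 against CIH and 2 against MI. Set A alone gave 2 against sham, 0 against CIH and 2 in the interaction, from 11 libraries with 1 MI and 1 MI+CIH heart, assumed to vary like the other groups; set B alone gave 0 in MI+CIH against MI. Second copies removed gave 6 in MI against sham, and leaving out sham 1 and MI 2 gave 114.

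Leaving out each library gave 0 to 113 in MI against sham, 0 to 0 in CIH against sham, 148 to 239 and 162 to 234 in MI+CIH against sham and CIH, 0 to 3 against MI and 0 to 0 in the interaction. In MI against sham, MI 2 (113 without it) and MI+CIH 1 (31) moved the count. In MI+CIH against MI, MI 3 (1, miR-206-3p) and MI+CIH 1 (3, miR-34b-3p, miR-34c-3p and miR-375-3p) did.

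With the set term, the 2 miRNAs of MI+CIH against MI became 0 under a pseudocount of 0.5, no filter, a mean of at least 50 RPM, median-of-ratios scaling, the replicate block or second copies removed. They became 5 with DESeq2 (miR-208a-3p, miR-499-5p, miR-9-5p and miR-9b-3p lower, miR-34c-5p higher), 31 with weights and 4 without sham 1 and MI 2 (miR-34b-3p, miR-34c-3p, miR-375-3p, miR-451a). TMM and edgeR called 2 each, miR-9-5p and its copy miR-9b-3p, sharing 0 with the 2. DESeq2 gave 1 against sham and 9 against CIH. Weights gave 1 in CIH against sham (miR-363-3p), 55 against sham, 82 against CIH and 41 in the interaction. No filter gave 1 in MI against sham (miR-7656-5p), and without sham 1 and MI 2 there were 21 against CIH. Leaving out each library with the set term gave 0 to 0 in MI against sham and in CIH against sham, 0 to 2 against sham, 0 to 12 against MI, 0 to 4 against CIH and 0 to 5 in the interaction. Against MI, the count was 10 without MI 1, 12 without MI+CIH 4, 1 without MI 3 or MI+CIH 3, and 0 without MI 4, MI+CIH 5, 6 or 7. Against sham it was 2 without sham 1 and 1 without MI 1, against CIH 3 and 4 without MI 1 and MI+CIH 4, and in the interaction 2 and 5 without the same hearts.

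Of the 24 lists called, 4 were called with an estimated correlation, all the muscle-enriched list. Other alternatives called 22 (median-of-ratios), 22 (TMM), 18 (replicate block), 24 (pseudocount 0.5), 27 (set term) and 24 (second copies removed), and 19 to 31 without each library. With the set term the muscle-enriched list in MI against sham changed direction (adjusted p 0.154, range over its alternatives 0.0212 to 0.404).

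Named miRNAs reversed as follows, for MI+CIH against sham unless CIH is named. Median-of-ratios: miR-30d-5p -0.92 (CIH -1.22), miR-24-3p -0.28 (CIH -0.47), miR-9-5p -1.18 (CIH -1.24), CIH miR-16-5p -0.50 and miR-27b-3p -1.26. TMM: miR-30d-5p -1.01 (CIH -1.31), miR-24-3p -0.37 (CIH -0.56), miR-9-5p -1.27 (CIH -1.33), CIH miR-16-5p -0.58 and miR-27b-3p -1.35. edgeR: miR-30d-5p -1.16 (CIH -1.41), miR-24-3p -0.53 (CIH -0.68), miR-9-5p -1.42 (CIH -1.44), miR-145a-5p -0.037, miR-379-5p -0.11, CIH miR-16-5p -0.51 and miR-27b-3p -1.35. DESeq2: miR-29c-5p -0.94, miR-30d-5p -0.99 (CIH -1.24), miR-24-3p -0.32 (CIH -0.49), miR-9-5p -1.19 (CIH -1.21), CIH miR-16-5p -0.39 and miR-27b-3p -1.20. Set term: miR-101b-3p 0.0015, miR-30e-5p 0.57, CIH miR-101a-3p 0.53, miR-486a-3p -0.45 (CIH -0.67), miR-486a-5p -0.48 (CIH -0.68), miR-25-3p -0.47 (CIH -0.34), CIH miR-92a-3p -0.18. Set A alone: miR-101a-3p 0.42 (CIH 1.08), miR-101b-3p 0.40, miR-208a-3p 0.17, miR-30e-5p 0.78, CIH miR-192-5p 0.0102, miR-486a-3p -0.48 (CIH -0.70), miR-486a-5p -0.48 (CIH -0.68), miR-25-3p -0.34 (CIH -0.21), CIH miR-92a-3p -0.20. Of the other values of named miRNAs, 2236 kept direction and side of the threshold under the alternatives of the plan other than leaving out a library. Of the rest, 107 were no longer past the threshold, 68 became so, and 218 changed sign with neither value past it. Under the added ones these were 732, 127, 22 and 109, and with a library left out 4690, 69, 35 and 126.

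Depth limits the low values: 3 reads are 0.165 to 1.51 RPM, so 0 reads of miR-375-3p in sham 2 and sham 5 allow up to 0.405 and 0.439 RPM.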

Other observations

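The counts of other splits of the samples were all chosen as tests after the results were seen. Of 100 splits, none other than the real one gave as many called miRNAs in MI+CIH against sham (real 204, highest other 142). The same held in MI+CIH against CIH (real 205, highest other 167) and for called lists (real 24, highest other 22). A random split thus rarely reached these 3 counts (1 of 100 each, the real one), though the margin for lists was small. Random splits also mix the library sets, so they do not tell group and set apart. For MI against sham and CIH against sham (highest other 0) and for the interaction (highest other 135) the real count was 0, which all 100 of 100 splits reach whatever the data, so these say nothing about chance.

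In MI+CIH against MI the real split called 0 as well, which 100 of 100 reach whatever the data, but another split called 221. That split put MI 2, MI+CIH 1, MI+CIH 6 and MI+CIH 7, which are hearts of sets A and C, against the rest, mostly set B, and so points to the library sets as a structure of the samples. With the set as a term, 7 of 90 exchanges within sets called as many as the real 2 (highest other 59), so chance cannot be excluded there. For the median of the muscle-enriched list with the set as a term, 2 of 90 exchanges lay as far from 0. These were the real one (-0.81) and 1 on the other side (0.86, the highest other), and the lowest other was -0.70. Few exchanges reached it, but the list was picked for this test after its camera result was seen. The exchanges in set A also rest on MI 2, whose label is in question.

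No library was a duplicate of another: 0 of 190 pairs were identical. The library closest to sham 1 was MI+CIH 1, at r = 0.986.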
